A study of Mus musculus with 2 samples.

How the data were processed

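Total RNA was extracted with Trizol from whole liver of BALB/c nude mice, per the labels' protocols, and biotin-labelled cRNA was made from 5 µg of it for an Affymetrix mouse expression array. The labels name 1 sample at day 0 and 1 at day 3 after removal of 70% of the liver. They do not say whether a sample came from 1 animal or a pool, and a sham-operated group was not analysed here. The arrays' number alone limits the precision: with 1 array per day there is no spread between samples, and no p-value or standard error was computed.

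The deposited values are probe set intensity values on a linear scale, made with GCOS software and the MAS5 algorithm per the submitters' processing notes. The versions and the scaling target are not given in the sources used here. The values had a mean of 500.0 on both arrays when the top and bottom 2% of the probe sets were trimmed, as a scaling of each array by 1 factor would give. MAS5 subtracts mismatch from perfect match probes, so low signals are noisy and their ratios large by chance. Detection calls were not used here. The median signal was 67.6 at day 0 and 68.3 at day 3.

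Probe sets were named through the array annotation supplied with the data: 34945 had 1 gene symbol, 932 had several and 9160 had no entry there, besides 64 control probe sets. Only probe sets with 1 symbol were used, and they named 18193 genes. The Entrez IDs of 34741 of them matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols. The values name no genome build, so no coordinates are given.

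Both arrays were used as deposited, without further scaling. Signals under a common floor, the higher of the 2 array medians (68.3), were set to the floor and log2 was taken. For comparison, 80 probe sets of olfactory and vomeronasal receptor genes, which liver is not known to use, had a 95th percentile of 63.1 at day 0 and 60.1 at day 3. Probe sets under the floor on both arrays were dropped, and each gene was represented by its probe set with the highest mean log2 signal. Of 12634 genes, 10722 were above the floor on both arrays, 998 at day 3 only and 914 at day 0 only. Across genes, which are not independent replicates, the log2 signals of the arrays had a Pearson correlation of 0.916. A gene counted as higher or lower at 2-fold. The spread between probe sets was the SD of the difference between the brightest 2 probe sets of a gene, divided by the square root of 2.

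The 40 gene lists held 1086 entries from textbook knowledge of liver biology and cell type markers, and 988 had a probe set with 1 symbol; some genes stand in several lists. For each list the median log2 ratio of the analysed members was computed, with genes under the floor on 1 array at their bound. Its percentile was taken among 10000 random lists of the same size, matched on 10 bins of mean log2 signal, and a list outside the central 95% of them is called outside. The 95% interval of a median came from 2000 bootstrap draws of the members and covers the spread between genes, not between animals.

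The genes named in the text followed a fixed rule. It took the 10 genes with the highest and the 10 with the lowest ratio among those above the floor on both arrays whose other probe sets went the same way, without clone and predicted-gene symbols. Of each list it took up to 3 members farthest in the direction of the list's median and up to 2 at least 2-fold the other way, and it added 30 genes of liver regeneration whatever their values. Some of these 30, among them Ccnb1 and Ddx3y, had no probe set with 1 symbol and were not analysed. Genes whose probe sets went at least 2-fold in both directions are said to disagree. The groups, the lists, the floor, the threshold, this rule and the alternatives were chosen before the data were examined. Additional genes named in the closing observations are marked there.

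The alternatives were median centring, quantile normalisation, loess (fraction 0.3), scaling to the hybridisation spikes, floors at the 25th and 75th percentile or from the receptor genes, use of genes above the floor on both arrays only, no floor with 16 added to each signal, the mean over probe sets, removal of probe sets marked as shared, and thresholds of 1.5-fold and 4-fold.

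The steps were tested on simulated data with 12149 genes, noise of the SD between probe sets and 200 genes with known ratios. These 200 were taken from genes well above the floor at day 0, and the noise was drawn independently for each probe set. Of genes with a true 2-fold difference 58% (higher) and 48% (lower) passed 2-fold, of those with a true 4-fold difference 100%, and of unchanged genes 1.95%. Of 100 unchanged lists of 30 genes 5% lay outside the central 95%, and a list raised 2-fold lay at percentile 100. Unchanged lists were random genes with independent noise, so a share near 5% follows from the design. The simulation held no differences between animals and no genes that move together, so its rates do not carry over to the real arrays. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.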

Results

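The series measured messenger RNA in whole liver of BALB/c nude mice, an athymic strain with few mature T cells, at day 0 and at day 3 after surgical removal of 70% of the liver. In rodents the remaining liver lobes regrow through cell division over the days that follow this operation. The submitters label day 0 as the control and day 3 as active regeneration, so the comparison asks which transcripts differ between these states. There was 1 array for day 0 and 1 array for day 3. No value below has a replicate, no test between the days was possible, and the day, the surgery and the animal cannot be told apart. Each array held 45101 probe sets, and 12634 named genes had a signal above a common floor of 68.3 on at least 1 array. At day 0, 49.8% of probe sets lay above the floor, and at day 3, 49.999% did. The floor was the higher array median, that of day 3, so the day 3 share follows from its definition. Neither share measures detection. All fold differences are day 3 against day 0. For a gene under the floor on 1 array the fold is a lower bound, written as at least that many fold.

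At day 3, 1625 genes (12.9% of those analysed) had at least 2-fold higher signal than at day 0, and 710 genes (5.62%) had at least 2-fold lower signal. Of the higher genes, 413 differed by at least 4-fold and 140 by at least 8-fold. Of the lower genes, 96 differed by at least 4-fold and 22 by at least 8-fold. The number of lower genes was 380 with spike scaling, 1834 with the floor at the 25th percentile, 406 at the 75th and 1770 with no floor, and that of higher genes was 574 with the floor at the 75th percentile. Higher genes made up 69.6% of those past 2-fold, against 58.2% after quantile normalisation, 55.8% after loess and 86.3% after scaling to the hybridisation spikes. The spikes moved the median log2 ratio of all genes from 0.08 to 0.36, so the gene lists below are set against random lists drawn from the same arrays.

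The largest difference among genes above the floor on both arrays was that of Lcn2, which encodes the iron-siderophore binding protein lipocalin 2 (328-fold higher, signal 90.7 at day 0 and 29724 at day 3). Next came Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex (97.6-fold), Ly6d, a surface protein (95.5-fold), Cdc20, an activator of that complex (64.6-fold), and the proliferation marker Mki67 (60.4-fold). Birc5, which encodes survivin, was 52.8-fold higher, the ribonucleotide reductase subunit gene Rrm2 35.4-fold, the mitotic kinase genes Pbk and Nek2 34.5-fold and 30.3-fold, with another probe set of Nek2 at a log2 ratio of 0.11, and the topoisomerase gene Top2a 29.2-fold. At the other end stood Hsd3b5, a steroid dehydrogenase (36.7-fold lower, signal 12511 at day 0 and 341.2 at day 3), the bile acid sulfotransferase Sult2a8 (35.2-fold lower), the uridine phosphorylase Upp2 (34.2-fold lower) and the cytochrome P450 gene Cyp2c54 (27.1-fold lower). Depp1 was 21.0-fold lower, the organic anion transporter Slco1a1 19.9-fold lower, the carboxylesterase Ces1e 16.7-fold lower, Adgrv1 13.6-fold lower, Abhd1 10.02-fold lower and the retinol dehydrogenase Rdh16 9.72-fold lower.

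**Figure D1:**
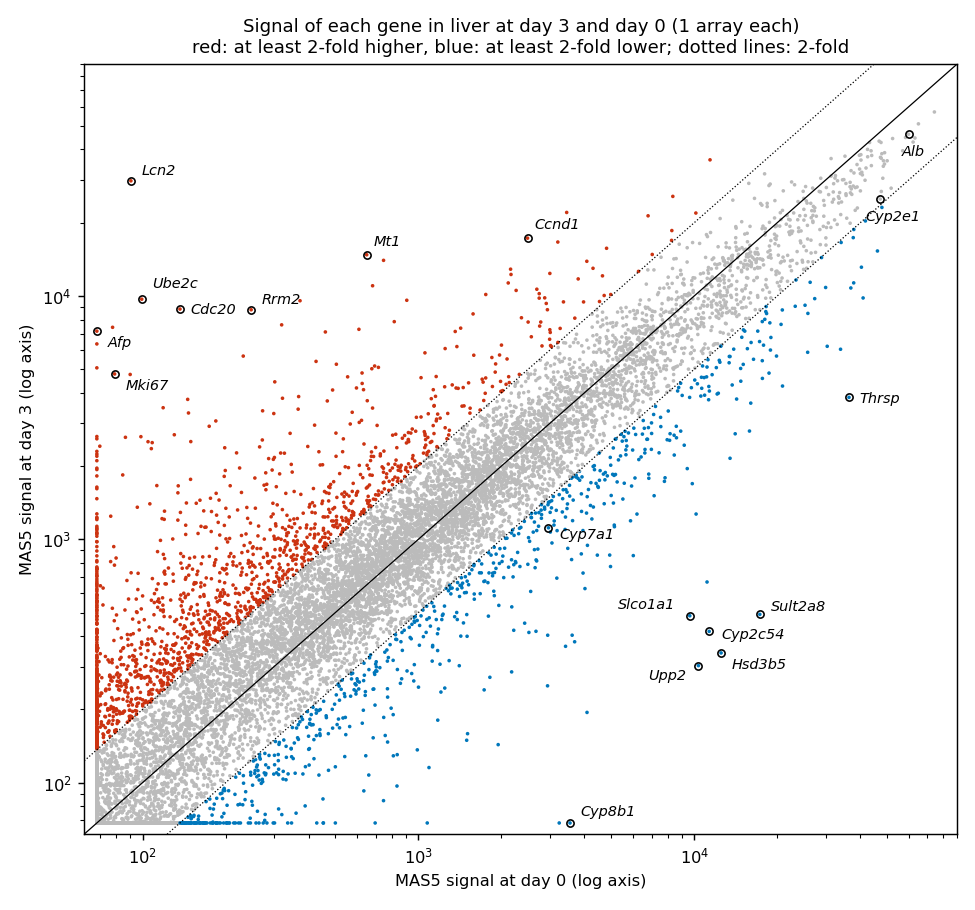
Signal of each of the 12634 genes on the day 0 array (x axis) and the day 3 array (y axis), both log axes of MAS5 signal with values under the floor drawn at the floor. Red points are the 1625 genes at least 2-fold higher, blue points the 710 at least 2-fold lower, and Lcn2 lies farthest above the diagonal at 328-fold.

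A second probe set above the floor on both arrays was present for 419 of the higher genes, and it went the same way for 375 and was at least 2-fold higher for 211. For the lower genes it was present for 227, went the same way for 209 and was at least 2-fold lower for 119. Between probe sets of 1 gene the log2 ratio had an SD of 0.435 per probe set (n = 4380 genes), from 0.514 in the third of genes with the lowest signal to 0.326 in the third with the highest. This SD covers differences between probe sets on these 2 arrays, not differences between animals.

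The control transcripts differed between the arrays in their 3' to 5' balance. The ratio of 3' to 5' signal of the poly-A spikes, bacterial RNAs added before labelling, was higher at day 3 in 8 of 8 probe set pairs, by 1.32 to 2.90 times (median 2.13). Their 5' probe sets had a median log2 ratio of −1.20 and their 3' probe sets one of −0.12. The −1.20 is set beside several gene lists below. Where each gene's probe set lies between these ends was not analysed, so −1.20 is not an expected value for any list. The same ratio was 1.41 at day 0 and 2.69 at day 3 for Gapdh, and 3.26 and 6.80 for beta-actin. For pyruvate carboxylase it went the other way, from 71.7 to 42.6. For the hybridisation spikes, which are added after labelling, the ratio at day 3 was 0.879 to 1.01 times that at day 0.

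**Figure D2:**
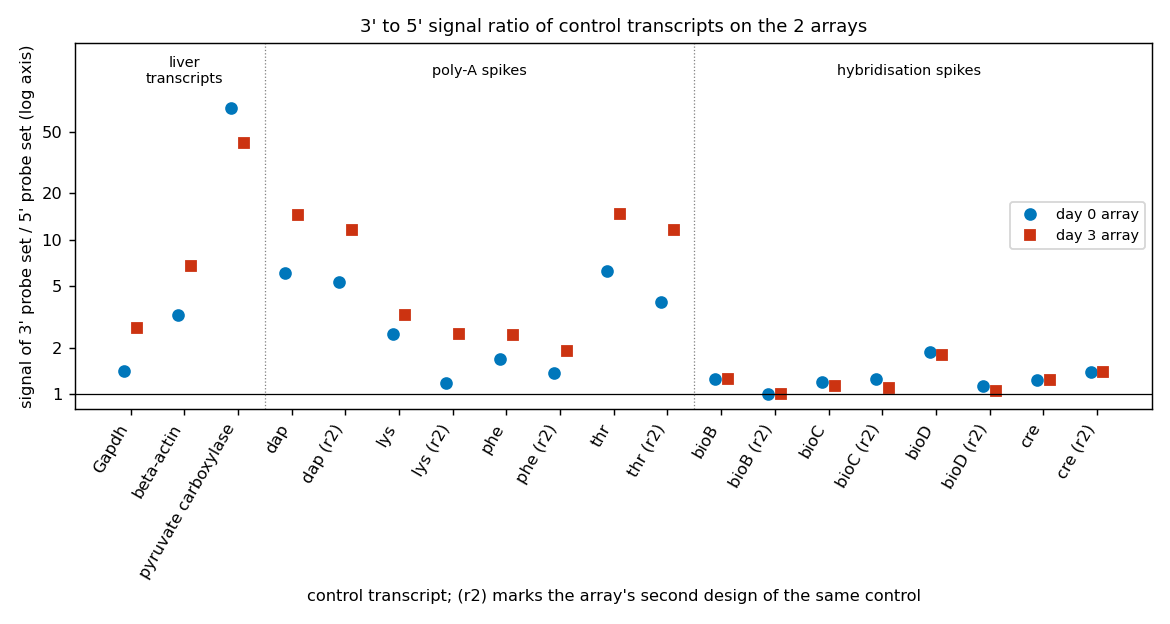
Ratio of 3' to 5' probe set signal (log axis) for 3 liver transcripts, 8 poly-A spike pairs and 8 hybridisation spike pairs, with a circle for the day 0 array and a square for the day 3 array. All 8 poly-A spike pairs, Gapdh and beta-actin lie higher at day 3. Pyruvate carboxylase, whose 5' signals lay near the floor, lies lower, and the hybridisation spikes lie at 0.879 to 1.01 times their day 0 ratio.

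The genes of cell division stood out most among the 40 gene lists. All 39 members of the mitosis list were at least 2-fold higher at day 3, with a median log2 ratio of 4.14 (95% bootstrap interval over members 3.49 to 4.59), and 25 of them lay under the floor at day 0. The median was 2.26 with the floor at the 75th percentile. Besides Ube2c and Cdc20, Ckap2, a spindle protein gene, was at least 74.2-fold higher. Of 31 DNA replication genes, 27 were at least 2-fold higher and none 2-fold lower (median 2.28, interval 1.93 to 2.77). Examples were Uhrf1, which couples replication to maintenance of DNA methylation (26.8-fold, another probe set at a log2 ratio of 2.09), Gins2, a part of the replicative helicase (at least 14.3-fold), and Pcna, the sliding clamp (3.26-fold). Ccna2, the S phase and mitotic cyclin, was at least 38.7-fold higher, and Foxm1, a transcription factor of mitotic genes, at least 5.24-fold. Both lists lay above all 10000 random lists of matched size and expression.

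Genes of the G1 phase and growth control were higher in 14 of 24 and under 2-fold in the other 10 (median 1.60, interval 0.67 to 2.36, above all 10000 random lists). Ccnd1, the D-type cyclin of G1, was 6.95-fold higher and reached a signal of 17280. Ccne1, the cyclin of S phase entry, was 3.86-fold higher and E2f1, a transcription factor of S phase genes, 6.14-fold. The pocket protein gene Rbl1 was 6.07-fold higher, with another probe set at a log2 ratio of 0.53. With the floor at the 75th percentile the median was 0.83. Of 21 p53 targets, 12 were at least 2-fold higher and 1 lower (median 1.24, interval 0.57 to 1.72, above all 10000 random lists). They included the cyclin-dependent kinase inhibitor gene Cdkn1a (5.25-fold), the antiproliferative gene Btg2 (7.49-fold) and Gtse1, which is also a cell cycle gene (10.4-fold), while Sesn1 was 2.01-fold lower on its main probe set and had a log2 ratio of 0.12 on another. Of 22 immediate early genes, 13 were higher and 1 lower (median 1.15, interval 0.14 to 1.61, above all 10000 random lists). Klf6 and Atf3, both transcription factors, were at least 9.59-fold and at least 9.501-fold higher, with another probe set of Klf6 at 0.74. Zfp36, an RNA decay factor, was 2.11-fold lower, and Myc had signals of 902 and 872. With the floor at the 75th percentile the medians of these lists were 0.80 (p53 targets) and 0.54 (immediate early genes). Among 22 apoptosis genes, 5 were at least 2-fold higher and none lower (median 0.45, percentile 98.1), with Bak1 3.75-fold, Apaf1 3.42-fold and Mlkl 3.15-fold higher. That list lay outside the central 95% of random lists in 7 of 11 alternative settings, and its median was 0.07 with the floor at the 75th percentile.

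Of 40 growth factors, cytokines and receptors of liver regeneration, 13 were at least 2-fold higher, 2 lower and 25 under 2-fold (median 0.20, percentile 75.3, and −0.02 with the floor at the 75th percentile). Inhbb, the activin B subunit, was 8.76-fold higher with another probe set at a log2 ratio of 0.58. Osmr, the oncostatin M receptor, was at least 5.08-fold higher. Fst, the activin antagonist follistatin, was at least 4.10-fold higher with another probe set at 0.35. Hgf, the hepatocyte growth factor, was 3.69-fold higher with another probe set at 0.08. The interleukin 6 receptor gene Il6ra was 3.25-fold lower and the growth hormone receptor gene Ghr 2.31-fold lower. Egfr was 1.77-fold lower, with probe sets from −1.495 to 0.11, and Met, the receptor of hepatocyte growth factor, 1.35-fold lower.

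Acute phase genes split. Of 28 measured, 11 were at least 2-fold higher, 2 lower and 15 under 2-fold, with a median log2 ratio of 0.34 (interval −0.07 to 1.61) that lay above 9998 of 10000 random lists and was 0.65 after loess. After Lcn2, the metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, were 25.7-fold and 22.7-fold higher, and the serum amyloid genes Saa2 and Saa1 7.41-fold and 5.97-fold. Crp, C-reactive protein, was 2.497-fold lower, and Hamp, the iron-regulating hormone hepcidin, 2.17-fold lower. Of 30 interferon-stimulated genes, 3 were at least 2-fold higher and none lower (median 0.23, percentile 80.4, and 0.06 with the floor at the 75th percentile), namely Cxcl10 (2.39-fold), Gbp3 (2.21-fold) and Oas2 (2.19-fold). Of 27 genes of endoplasmic reticulum and integrated stress, 5 were higher and 3 lower (median 0.04, percentile 75.8, and −0.04 after median centring), and the list lay within the central 95% in 10 of 11 alternative settings. Psat1 and Phgdh, enzymes of serine synthesis, were at least 6.26-fold and at least 3.09-fold higher, with another probe set of Phgdh at 0.61. The transcription factor gene Ddit3 was 3.33-fold higher, while Chac1, a glutathione-degrading enzyme gene, was 5.00-fold lower and Herpud1 2.84-fold lower. Of 20 NRF2 and glutathione genes, 5 were higher and none lower. Their median was −0.02 (percentile 76.95) and above 0 after quantile normalisation, loess and spike scaling, and their mean was 0.31. Hmox1, the heme oxygenase gene, was 3.33-fold higher and Cbr3 at least 3.59-fold, while the transferase genes Gsta3, Gstm4 and Gstm1 were 1.56-fold, 1.45-fold and 1.40-fold lower.

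Genes of lipid and sterol synthesis were lower at day 3. On the same arrays the 5' probe sets of the poly-A spikes had a median of −1.20. Of 24 genes of fatty acid and triglyceride synthesis, 10 were at least 2-fold lower and 2 higher (median −0.84, interval −1.58 to −0.27, below all 10000 random lists). Thrsp, a lipogenic regulator, was 9.502-fold lower, the phosphatidate phosphatase Lpin1 8.94-fold, the acetyl-CoA synthetase Acss2 4.74-fold with another probe set at a log2 ratio of 0.80, and the fatty acid synthase Fasn 2.98-fold. The lipid droplet gene Cidec was at least 3.41-fold higher and the desaturase Scd2 2.24-fold, with another probe set of Scd2 at −0.38. Of 19 genes of cholesterol synthesis and uptake, 6 were lower and none 2-fold higher (median −0.70, interval −1.24 to −0.41), and 2 of 10000 random lists lay below it. Fdps, the farnesyl diphosphate synthase, was 5.81-fold lower, the sterol reductase Tm7sf2 4.38-fold and the sterol desaturase Sc5d 2.79-fold. After spike scaling the medians of these lists were −0.55 and −0.41. Of 21 genes of fatty acid oxidation and ketogenesis, 4 were higher, 1 lower and 16 under 2-fold. Their median was −0.08 (percentile 70.1), above 0 after quantile normalisation, loess and spike scaling, and their mean was 0.20. Pdk4, a kinase that restrains pyruvate oxidation, was 10.3-fold higher and the acyl-CoA thioesterase Acot2 7.43-fold, while the nuclear receptor gene Ppara was 3.58-fold lower, the thiolase Acaa1b 1.77-fold and Etfdh 1.71-fold lower.

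Bile acid genes were also lower: 10 of 23 by at least 2-fold, with 1 higher (median −0.86, interval −1.36 to 0.12, below all 10000 random lists). Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, went from a signal of 3545 to under the floor and was at least 51.9-fold lower. Cyp7b1, of the alternative synthesis pathway, was 4.42-fold lower and Cyp7a1, the rate-limiting enzyme of the classic pathway, 2.66-fold. Slc51b, a subunit of the basolateral bile acid exporter, was at least 8.43-fold higher. The list's median was −0.56 after spike scaling and lay above the −1.20 of the 5' spike probe sets.

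Among 14 genes of gluconeogenesis and the fasting response, 3 were at least 2-fold lower and 1 higher (median −0.70, interval −0.95 to −0.33, and −0.41 after spike scaling), and 6 of 10000 random lists lay below, beside a median of −1.20 for the 5' spike probe sets. G6pc, which releases free glucose, was 4.88-fold lower, the aminotransferase Got1 2.57-fold lower and the tryptophan dioxygenase Tdo2 2.05-fold lower, Pck1 was 1.76-fold lower, and Igfbp1, an insulin-like growth factor binding protein, was 2.70-fold higher. Of 18 genes of glycolysis and glucose uptake, 5 were higher and 2 lower (median 0.58, interval 0.08 to 0.92, above 9987 of 10000 random lists). Pkm, the pyruvate kinase of most non-liver tissues, was 6.24-fold higher and Hk2, a hexokinase low in adult hepatocytes, 3.34-fold, while Pklr, the liver pyruvate kinase, was 4.59-fold lower and Slc2a2, the hepatocyte glucose transporter, 2.13-fold. Pfkfb3 was 2.75-fold higher on its main probe set and had a log2 ratio of −0.21 on another. The list lay outside the central 95% in 9 of 11 alternative settings. Its median was 0.03 (percentile 42.7) without probe sets marked as shared between transcripts and 0.22 with the floor at the 75th percentile.

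Of 32 genes of the urea cycle and amino acid breakdown, 11 were at least 2-fold lower and none 2-fold higher (median −0.54, interval −0.99 to −0.33, and −0.25 after spike scaling), and 1 of 10000 random lists lay below, beside a median of −1.20 for the 5' spike probe sets. Afmid, a kynurenine pathway enzyme, was 4.48-fold lower with another probe set at −0.18, Mat1a, the liver methionine adenosyltransferase, 3.87-fold and Prodh, proline dehydrogenase, 3.77-fold. Of 33 genes of oxidative phosphorylation, 1 was 2-fold lower and 32 were under 2-fold (median −0.35, percentile 6.88, and −0.06 after spike scaling), with Sdhb 2.16-fold, Atp5c1 1.69-fold and Ndufb5 1.67-fold lower. Of 29 genes of ribosome biogenesis, 5 were at least 2-fold higher and none lower (median 0.30, percentile 93.8, and 0.59 after spike scaling), with the nucleolar protein genes Nop58 3.53-fold, Rrp12 2.52-fold and Nolc1 2.45-fold higher, the last with another probe set at −0.03.

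Xenobiotic enzymes were lower in 12 of 29 and higher in 1 (median −0.88, interval −1.17 to −0.57, and −0.54 after loess, below all 10000 random lists), beside −1.20 for the 5' spike probe sets. After Cyp2c54, Cyp2c50 was 7.02-fold lower and Cyp1a2 5.62-fold, whereas Cyp3a13 was 2.89-fold higher. Cyp2e1 was 1.89-fold lower, and Cyp3a11 had a log2 ratio of −0.22, or 0.13, 0.17 and 0.07 after quantile normalisation, loess and spike scaling. The secreted plasma proteins of hepatocytes differed little: 32 of 35 were under 2-fold, 1 higher and 2 lower (median −0.37, interval −0.50 to −0.32, percentile 3.89). The median was −0.04 after loess, and the list lay within the central 95% in 9 of 11 alternative settings. Alb, albumin, was 1.30-fold lower, with log2 ratios of 0.06 and 0.05 after quantile normalisation and loess. The complement gene C8b was 3.30-fold lower, Fetub 2.01-fold and Ces1c 1.73-fold lower, and the apolipoprotein gene Apoa4 6.39-fold higher. Of 19 hepatocyte transcription factors, 3 were lower and 1 higher (median −0.29, percentile 4.42, and 0.00 after spike scaling), and the list lay within the central 95% in 9 of 11 alternative settings. Cebpa was 2.81-fold lower and the bile acid receptor gene Nr1h4 2.01-fold lower, while Prox1 was 2.23-fold higher.

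Genes of the pericentral and periportal zones of the liver lobule went both ways. Of 25 pericentral genes, 3 were higher and 5 lower (median 0.29, percentile 99.2, mean −0.08). The median was −0.08 with the floor at the 75th percentile and −0.07 with the mean over probe sets, and the list lay above the central 95% in 6 of 11 alternative settings. Slc1a4, a neutral amino acid transporter, was 20.6-fold higher and Lect2 and Lhpp 2.04-fold and 2.03-fold, while Slc1a2, a glutamate transporter, was 8.86-fold lower and Glul, glutamine synthetase, 2.39-fold lower. Of 24 periportal genes, 4 were higher and 6 lower (median −0.35, interval −0.82 to −0.19, percentile 4.71). This list lay below the central 95% in 2 of 11 alternative settings, and its median was −0.09 after quantile normalisation and −0.03 after loess. Pigr, the polymeric immunoglobulin receptor, was 4.89-fold lower and Etnppl, a phospholyase, 4.56-fold lower. The probe sets of Hsd17b13, a lipid droplet enzyme gene, disagreed, with log2 ratios of 4.01 and −1.36.

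Male-biased liver genes were lower at day 3. Of 17, 11 were at least 2-fold lower and 1 higher (median −1.31, interval −2.12 to −0.82, below all 10000 random lists). The 5' probe sets of the poly-A spikes, at a median of −1.20, lay within that interval. Hsd3b5 and Slco1a1 led, the glucuronosyltransferase Ugt2b38 was at least 6.27-fold lower, and Bcl6, a repressor that is itself male-biased, was 3.76-fold higher with another probe set at 0.41. Female-biased genes went both ways, with 6 of 17 higher and 5 lower (median 0.43, interval −1.05 to 1.73, above 9754 of 10000 random lists). Prom1, a stem cell surface marker that also stands in the fetal liver and progenitor list, was at least 93.0-fold higher. The estrogen sulfotransferase Sult1e1 was at least 23.6-fold higher and Cyp4a14 5.78-fold, while Cyp2b13 was at least 3.78-fold lower and the receptor gene Lifr 3.30-fold lower with another probe set at −0.08. This list's place outside the central 95% held in 5 of 11 alternative settings, and its median was −0.08 without shared probe sets. The sex chromosome genes were under 2-fold in 4 of 4 (median −0.04, percentile 30.2, and 0.11 after spike scaling; mean 0.04). The Y-linked genes Eif2s3y and Kdm5d had signals of 1386 and 415 at day 0 and 1127 and 337 at day 3, and Xist, the transcript of the inactive X chromosome, had 62.2 and 79.6, near the floor on both arrays.

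Clock genes differed in both directions, with 8 of 17 at least 2-fold lower and 3 higher (median −0.93, interval −1.25 to −0.19, below all 10000 random lists), beside −1.20 for the 5' spike probe sets. Dbp, an output transcription factor of the clock, was 4.51-fold lower, the repressor Cry2 3.16-fold and Ciart 2.89-fold. Clock and Arntl, which encode the activating pair of the clock, were 2.85-fold and 2.69-fold higher, with another probe set of Clock at a log2 ratio of 0.68. The labels do not give the time of day at which the livers were taken.

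**Figure D3:**
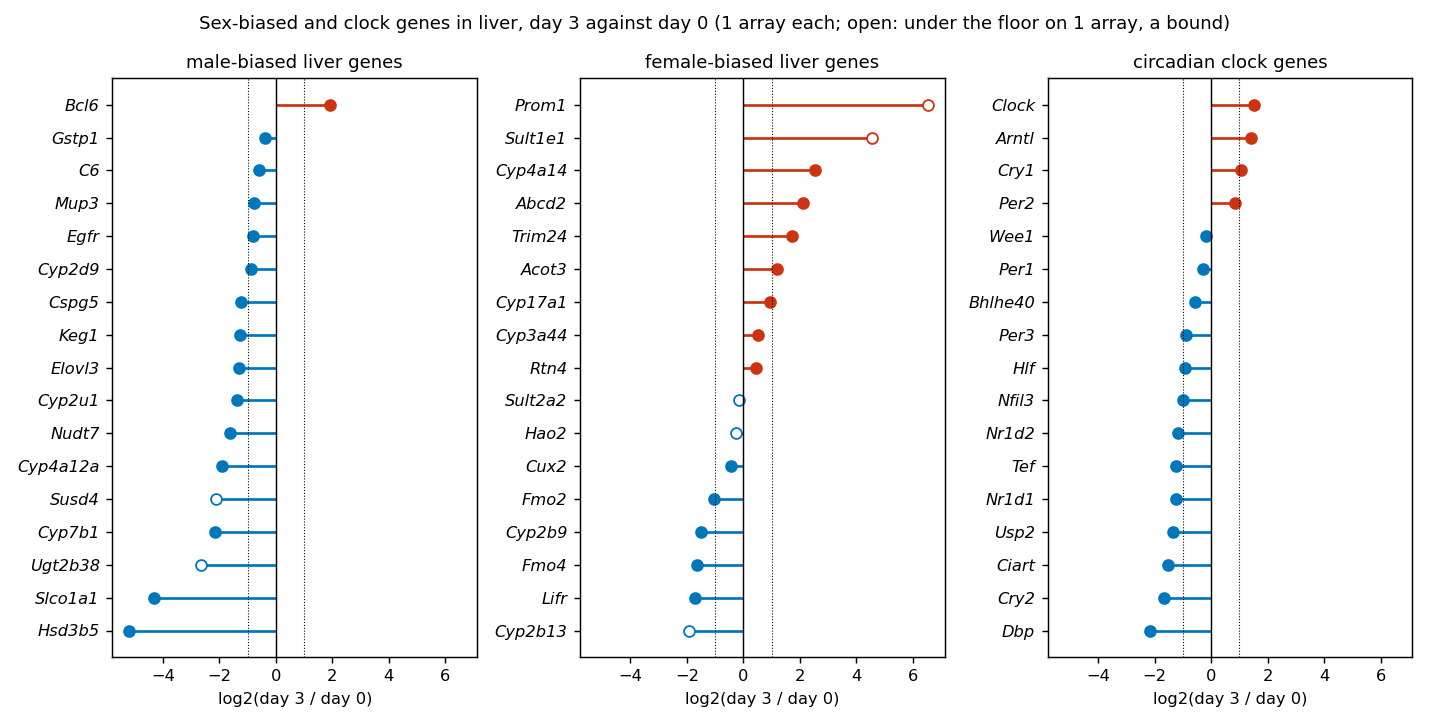
Log2 ratio of day 3 to day 0 for each analysed gene of the male-biased, female-biased and clock lists, 1 array per day, with dotted lines at 2-fold and open circles for genes under the floor on 1 array, whose ratio is a bound. Of 17 male-biased genes 11 lie at or beyond 2-fold lower, while the female-biased and clock lists hold genes beyond 2-fold on both sides.

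Fetal liver and progenitor genes were higher in 13 of 19 and lower in none (median 1.37, interval 0.90 to 2.64, above all 10000 random lists). Afp, alpha-fetoprotein, the main plasma protein of fetal liver, had a signal of 19.02 at day 0 and 7169 at day 3, at least 105-fold higher. The lowest log2 ratio among the 4 probe sets of Afp was 0.95. Prom1, also in the female-biased list, was at least 93.0-fold higher, and Tnfrsf12a, the receptor of the cytokine TWEAK, 10.3-fold. Of 16 cholangiocyte markers, 10 were higher and none lower (median 1.19, interval 0.61 to 1.37, above 9999 of 10000 random lists). Among the higher were Tspan8 (at least 8.03-fold, another probe set at 0.79), Epcam (at least 6.57-fold, another probe set at −0.06) and Cldn7 (3.43-fold). All 3 had low signals at day 0, and with the floor at the 75th percentile the list's median was 0.08 (percentile 48.0). The cholangiocyte list shares Epcam, Krt7, Krt19 and Sox9 with the fetal liver and progenitor list.

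Markers of stellate cells and fibroblasts were higher in 21 of 32 and lower in 1 (median 1.48, interval 1.03 to 2.28), and extracellular matrix genes in 22 of 29 with none lower (median 1.45, interval 1.16 to 1.98). Both lay above all 10000 random lists and share the fibrillar collagen genes Col1a1 (at least 16.6-fold), Col3a1 (10.6-fold) and Col1a2 (10.4-fold). The probe sets of Nes, the intermediate filament gene nestin, disagreed, at −1.46 and 1.89. Of 27 Kupffer cell and macrophage markers, 12 were at least 2-fold higher and none lower (median 0.93, interval 0.07 to 1.21, above all 10000 random lists). The endotoxin co-receptor gene Cd14 was 9.61-fold higher, the scavenger receptor gene Marco 9.35-fold and the lysozyme gene Lyz2 3.88-fold. The plasma protein genes of hepatocytes had a median of −0.37 on the same arrays.

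The endothelial, neutrophil, lymphocyte, and erythroid and megakaryocyte lists lay within the central 95% of random lists. Of 32 endothelial markers, 4 were higher, 1 lower and 27 under 2-fold (median 0.11, percentile 35.0, and −0.05 after quantile normalisation and after loess). Cd34 was 3.29-fold higher, Vwf, von Willebrand factor, 2.45-fold and the Wnt agonist Rspo3 2.39-fold, while the sinusoidal nuclease Dnase1l3 was 2.62-fold lower. Of 11 neutrophil markers, 5 were higher and none lower (median 0.34, interval −0.08 to 3.10, percentile 78.8, within the central 95% in 8 of 11 alternative settings and at a median of 1.53 after spike scaling), led by Lcn2, which hepatocytes also express, the granule protease Prtn3 (at least 18.03-fold) and S100a8 (at least 8.57-fold). Of 12 T, NK and B cell markers, 1 was higher and 1 lower (median −0.22, interval −0.57 to 0.19, percentile 6.68, and 0.03 over genes above the floor on both arrays). Thy1 was at least 2.74-fold higher, and the immunoglobulin heavy chain gene Ighm 3.94-fold lower with another probe set at 0.43. Ccl5 and Ms4a1, a T cell and a B cell gene, were at least 1.70-fold and at least 1.502-fold lower. Of 14 erythroid and megakaryocyte markers, 2 were higher and 3 lower. Their median was 0.13 (percentile 57.9), −0.03 after quantile normalisation and after loess, and their mean was −0.16. The platelet factor Pf4 was 3.26-fold higher, the transferrin receptor gene Tfrc 2.53-fold and the carbonic anhydrase Car2 1.53-fold, while Car1 was at least 7.32-fold lower and the erythroid transcription factor gene Klf1 at least 4.01-fold lower.

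Among tissues that dissection could carry along, 19 acinar pancreas markers had a probe set with 1 symbol. Only 5 were above the floor on at least 1 array, and 2 on both, with 1 higher and 2 lower (median −0.86, percentile 0.57). The rest were under the floor on both arrays. Cela1 was 2.81-fold lower, Cela2a at least 2.36-fold and Cela3b 1.82-fold, while Spink1, a trypsin inhibitor, was at least 7.52-fold higher. At day 0 Cela1 had a signal of 5182, but Cela2a and Cela3b only 161 and 143, so a fall of pancreas tissue cannot be read from this list. That list lay outside the central 95% of random lists in 6 of 11 alternative settings, and its median was −0.21 with the floor from the receptor genes. Of 19 adipose, muscle and peritoneum markers with such a probe set, 10 were above the floor on at least 1 array. Of these, 1 was higher, 1 lower and 8 under 2-fold (median 0.09, percentile 74.2, and −0.14 over genes above the floor on both arrays). Fabp4, an adipocyte and endothelial fatty acid carrier, was 5.87-fold higher, Lrrn4 and Ckm at least 1.39-fold and at least 1.38-fold higher, and Car3, a carbonic anhydrase that liver also expresses, 3.02-fold lower.

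**Figure D4:**
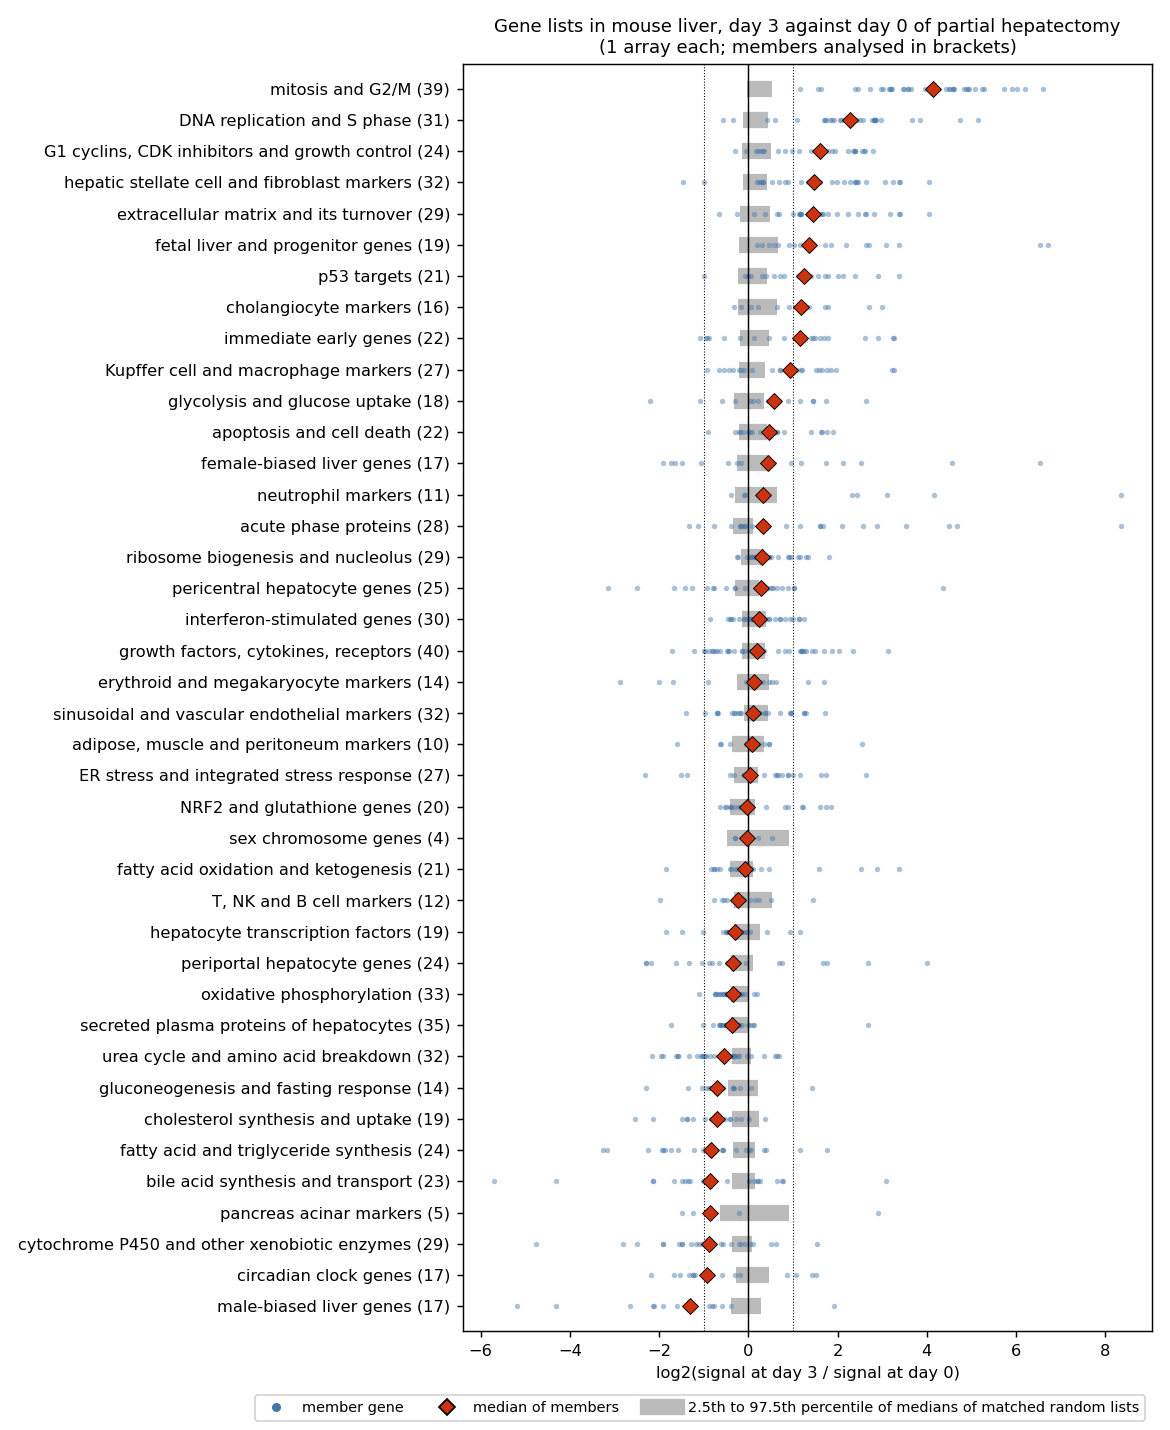
Log2 ratio of day 3 to day 0 for the 40 gene lists, sorted by median: blue points are member genes, red diamonds the list medians, and grey bars the central 95% of medians of 10000 random lists matched on size and expression. The mitosis list lies highest at 4.14 and the male-biased list lowest at −1.31.

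Across the 40 lists, 15 medians lay above the central 95% of random lists, 9 below and 16 within. Lists of unrelated genes would place 2 outside. Members of 1 list can move together and lists share genes, so this count does not exclude chance differences between 2 livers. Of the 9 below, the male-biased list had a median of −1.31 and the other 8, which include those of lipid, sterol, bile acid, glucose, amino acid and xenobiotic metabolism, had medians of −0.93 to −0.54, against −1.20 for the 5' probe sets and −0.12 for the 3' probe sets of the poly-A spikes. The distance of each gene's probe set from the 3' end was not analysed here. Against random lists not matched on expression, the acute phase (percentile 95.6), pericentral (91.2) and female-biased (96.1) lists lay within the central 95%. The plasma protein (0.02), hepatocyte transcription factor (1.58), periportal (0.18) and oxidative phosphorylation (0.04) lists lay below it. These percentiles describe 2 arrays and are not tests between the days.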

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

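Of 440 list medians under 11 alternatives, 408 stayed inside the bootstrap interval of the main value, 29 left it and 3, of lists outside the central 95% of random lists, changed sign, and of 1849 values of 176 named genes 1705 moved by less than the SD between probe sets. Of the 24 such lists, 19 (floor at the 75th percentile) to 23 (quantile normalisation, loess and no floor) stayed outside on the same side. Median centring shifts all genes and random lists alike, so it kept all 24 by design. It is 1 of the 11 alternative settings in each count of settings and can change no percentile there. No paired analysis was possible because each day had 1 array. The causes of the shifts were not tested. A gene under the floor on 1 array has only a bound, as most of the mitosis list had.

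The number of lower genes was 380 with spike scaling, 1834 with the floor at the 25th percentile, 406 at the 75th and 1770 with no floor, against 710, and that of higher genes 574 with the floor at the 75th percentile, against 1625. At 4-fold there were 413 higher and 96 lower genes, and at 1.5-fold 3028 and 1797. Lists outside the central 95% kept their direction except in 3 cases. Pericentral genes had a median of −0.076 with the floor at the 75th percentile and −0.066 with the mean over probe sets, and female-biased genes −0.080 without shared probe sets. Nes had 0.22 with the mean over probe sets. Of the 16 lists within the central 95%, 10 changed sign under at least 1 alternative.

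Among values that left their interval, median centring gave −0.040 for endoplasmic reticulum stress. Quantile normalisation gave −0.082 for plasma proteins, −0.086 for periportal genes and −0.18 for oxidative phosphorylation, and loess gave −0.035, −0.025 and −0.17 for these and −0.54 for xenobiotic enzymes. Spike scaling gave −0.41 for cholesterol synthesis, 0.21 for fatty acid oxidation, −0.25 for the urea cycle, −0.080 for plasma proteins, 0.0024 for hepatocyte transcription factors, 1.38 for cholangiocytes, 0.59 for pericentral genes, −0.060 for periportal genes, 1.22 for macrophages, 0.35 for endothelium, 0.47 for interferon-stimulated genes, 0.59 for ribosome biogenesis and −0.063 for oxidative phosphorylation. The mitosis list had 4.92 with the floor at the 25th percentile, 2.26 at the 75th, 4.60 with genes above the floor on both arrays, 4.68 with no floor and 3.03 with the mean over probe sets. With the floor at the 75th percentile, DNA replication had 1.90 and cholangiocyte markers 0.080, and without shared probe sets glycolysis had 0.027.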

Other observations

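All tests in this part were chosen after the results were seen, as were the genes named in it that the report does not name.

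Among genes outside the lists, the chemokine gene Cxcl14 was at least 32.2-fold higher, Wfdc3 at least 26.7-fold with another probe set at a log2 ratio of 0.21, the protease inhibitor gene Slpi 23.8-fold, the trefoil factor gene Tff3 9.16-fold and Wfdc18 at least 7.07-fold. Anxa2 was 11.98-fold higher, Lgals1 9.59-fold, Tagln2 9.42-fold, S100a6 7.72-fold, Tubb2a 5.18-fold and Tuba1a 4.84-fold. These genes were chosen after their values were seen and stand for no gene group. Tubb6 was 14.7-fold higher on its main probe set and had a log2 ratio of −0.72 on another. Besides Psat1 and Phgdh, Psph, the last enzyme of serine synthesis, was 5.97-fold higher and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, 8.01-fold, and Shmt2, a mitochondrial serine hydroxymethyltransferase, had signals of 6590 and 5709 on its main probe set and log2 ratios of −0.53 to 0.99 over 4 probe sets. Mthfd2, a mitochondrial folate enzyme gene, was 1.84-fold higher, with another probe set at 1.55.

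The lower genes outside the lists included Rgs16, a regulator of G protein signalling (at least 47.5-fold), and the regulatory subunit gene Ppp1r3g of glycogen metabolism (at least 6.63-fold). Txnip, an inhibitor of thioredoxin, was 6.40-fold lower, Crebrf 6.70-fold, Arrdc3 5.44-fold, Klhl24 5.24-fold with another probe set at −0.21, and the autophagy gene Gabarapl1 3.26-fold. The pyruvate dehydrogenase kinase genes Pdk2 and Pdk1 were 4.13-fold and 3.47-fold lower, against the 10.3-fold higher Pdk4. The 4 probe sets of Pdk1 had log2 ratios of −2.52 to −0.39. The major urinary protein genes Mup5 and Mup10, which are near-identical to other genes of their family, were at least 10.2-fold and 6.26-fold lower. Within the macrophage list the class II antigen presentation genes Cd74, H2-Aa, H2-Eb1 and H2-Ab1 had log2 ratios of −0.93, −0.65, −0.54 and −0.43, while the complement genes C1qa, C1qb and C1qc had 1.02, 1.19 and 1.76.

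Male-biased liver genes were lower at day 3. Animals of different sex would need a large difference in Xist or the Y-linked genes, and the largest of 4 such log2 ratios was 0.52 in size, that of Uty. A lower share of hepatocyte RNA would lower other hepatocyte genes as much. Without C6, which both lists hold, the median of 16 male-biased genes (−1.34) minus that of 34 plasma proteins (−0.37) was −0.96 (95% bootstrap interval −1.76 to −0.51). Male-biased genes were thus lower than plasma protein genes, but both list medians had been seen before. The lists were also not matched on signal. Central 95% ranges of matched random lists were −0.38 to 0.28 for male-biased genes and −0.39 to −0.0008 for plasma proteins. A lower share is therefore not excluded. Shorter labelled RNA at day 3 stays open. The median of −1.31 over all 17 genes had an interval of −2.12 to −0.82, which holds the −1.20 of the 5' spike probe sets. The 3' spike probe sets had −0.12, and the place of each gene's probe set between these ends was not analysed. An interval that holds −1.20 therefore does not show that shorter RNA lowered these genes. Shorter RNA may equally bear on the 8 other lists below the central 95%, with medians of −0.93 to −0.54. Xenobiotic enzymes (median −0.88, interval −1.17 to −0.57) and bile acid genes (−0.86, interval −1.36 to 0.12) were lower as well. Both lists share genes with the male-biased list, such as Cyp4a12a and Cyp7b1. A change of the male pattern is therefore not told apart from a wider fall of hepatocyte metabolic genes. Also open is the hypothesis that the operation itself may lower the male pattern of liver expression. With 1 animal or pool per day it cannot be separated from a difference between animals.

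Of the 17 clock genes, 15 were sorted by phase after their values had been seen, and the rest were left out. The medians of the phases had opposite signs. The median of 4 genes that peak with Arntl was 1.24, that of 11 genes that peak with Dbp was −1.19, and they differed by 2.43 (interval 0.18 to 2.76). This is consistent with livers taken at different times of day, although Nfil3 (−1.003) and Per2 (0.86) went against their phase. A lower share of hepatocyte RNA would lower the plasma proteins as much, but the median of the 11 genes minus that of the plasma proteins was −0.81 (interval −0.97 to −0.21). These lists were not matched on signal either, so a lower share is not excluded. The 4 genes, with an interval of −1.003 to 1.51 that spans 0, decide nothing on it and do not establish a rise. The time of day and an effect of the operation or of feeding on the clock stay open, and so do both for metabolic genes under clock control, as does shorter labelled RNA for the lower genes.

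Cell cycle genes were higher at day 3, and the cells that carried them were not identified. Dividing erythroid precursors would bring erythroid genes, but 9 such genes had a median of 0.077 (interval −2.004 to 0.54), 0 of them 2-fold higher and 3 lower, with the brightest, Alas2, at signals of 8932 and 2783. Tfrc, which other dividing cells also express, was not among the 9 and was 2.53-fold higher, and with it the median was 0.13 (interval −1.68 to 0.54). Dividing lymphocytes would bring T, NK and B cell genes, whose median over 12 was −0.22 (interval −0.57 to 0.19), with 12 others under the floor on both arrays. Many of the 12 analysed genes lay near the floor, so a small share of dividing lymphocytes could go unseen. Macrophage and stellate cell markers were higher, with a median of 1.19 over 59 genes (interval 0.88 to 1.59), against 4.14 for the mitosis list. Dividing cells of these types may contribute, but such markers can also rise without division, so the rise does not decide it. Of the 59, 53 were above the floor at day 0 and 9 stand in another list. Division of hepatocytes, the usual account of day 3, was not tested here and stays open beside these cell types.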
